A study of Mus musculus with 9 samples.

How the data were processed

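The study compared 3 treatments of young adult mice, with 12 mice per treatment and 36 in all. The gastrocnemius was taken 14 days after surgery from animals that had not been fasted. Per the labels' protocols, total RNA was purified with a spin column kit, equal amounts of 4 µg from 3 animals were pooled for each array, and 12 µg were labelled by the standard Affymetrix protocol. The levator ani, a perineal muscle, was also dissected and is not analysed here. Groups and replicate numbers were taken from the sample titles. The labels give no scan date, batch or time of day.

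The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes, and its version is not given in the sources used here. RMA corrects the background, quantile-normalises all arrays together and summarises the probes of a probe set, so a shift common to a whole array is removed and an aberrant array can move the reference for the others. Array medians lay between 3.15 and 3.26. The values were used as deposited, with no further normalisation. Arrays have no read depth, and their number, 3 per group, limits the precision.

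The table held 45101 probe sets, of which 64 were controls. The platform annotation given here lists 34945 probe sets with 1 gene, 932 with several and leaves 9160 unlisted besides controls. Symbols were checked through the gene identifiers of the reference gene table, where 204 probe sets found no match and kept the annotation's symbol. Each gene was represented by the probe set with the highest mean over all arrays among those listed to it alone, which left 18193 genes. Signs of a gene's other probe sets were compared with the one used. Unlisted probe sets were tested separately, and 3 genes of the rule below had no probe set listed to them alone and are not reported here.

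Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 9 arrays with the group as the only term, as the design text names a one-way analysis with 3 pairwise comparisons. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 18193 genes of a comparison with a threshold of 0.05. An F test over the groups used the same fit. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists of a comparison, each with at least 5 measured members. Members were also adjusted over the list alone. That adjustment did not extend over the 31 lists or the 3 comparisons, so some such passes can arise by chance. Lists cover hormone response, muscle growth and breakdown, metabolism and markers of other cell types, and were written, like the tests of the comparisons and most alternatives, before the data were examined. The labels call the arrays independent biological replicates, so p-values measure the spread between pools of 3 animals.

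Genes were named by a rule also fixed then. Where fewer than 10 genes passed, the 5 genes with the smallest p in each direction were named, leaving out predicted and clone names. From each list described, up to 4 members passing over all genes or over the list alone were named, or up to 3 with the smallest p where none passed. A fixed set (Igf1, Fbxo32, Trim63, Odc1, Smox, Fkbp5, Myh1, Myh2, Myh4 and Myh7) was named in every comparison.

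The fits were repeated with a block for the replicate number, only the 2 groups compared, all probe sets, the mean of a gene's probe sets, no probe sets with the suffix for cross-hybridisation, no dim genes, renewed quantile normalisation, median centring, an intensity trend, robust variances, analysis of variance without moderation, limma array weights and each array left out in turn. For lists, camera with an estimated correlation and the directional fry test were added to these, with fry's test for changes in either direction beside them. Leaving out sham 2 and testosterone 2 together, and setting castration against the mean of the other groups, were chosen after the data had been seen. Where a group kept 1 or 2 arrays the pooled spread of all groups was used.

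Arrays were checked for duplicates: any 2 arrays shared at most 5.78% of identical values and correlated between 0.967 and 0.995. Opposite signs and overlaps from shared castration arrays were simulated 100 times with unchanged groups, the overlap of the 50 smallest p-values after its count had been seen. Simulated genes varied independently of each other. Other groupings of the arrays were refitted, with at most 100 drawn. Intervals of medians are 95% bootstrap intervals over genes with 10000 draws, and genes are not independent replicates. Scripts were tested on simulated data for castration against sham over 18193 genes, with 50 genes changed per size. The fit recovered 44, 46, 50 and 50 of 50 genes at log2 changes of 1, 1.5, 2 and 3, with 6 false calls in all, and array weights recovered 47, 48, 50 and 50 with 9. A list shift of 0.3 simulated in testosterone against castration was recovered with 0 other lists called. Genes were simulated independently and with moderated spreads, so these runs check the scripts only. They do not measure power or false calls on the real arrays, where genes can vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.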

Results

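Gene expression was measured in the gastrocnemius, a calf muscle, of young adult CD-1 mice, an outbred stock, at day 14 after surgery. Sham mice had sham surgery and a placebo pellet. Castration mice were castrated and received a placebo pellet. Testosterone mice were castrated and received a 2.5 mg testosterone pellet with 60-day release straight after surgery. Each group had 3 Affymetrix arrays, and each array held RNA pooled from 3 animals, so 27 of the 36 treated mice were measured. An SD below is therefore the spread between pools, not between animals, and 3 arrays per group limit the precision. Expression is given as log2 values, which ran from 2.22 to 14.24 over all probe sets and arrays, and 18193 genes were tested.

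Arrays sham 2 and testosterone 2 stood apart from the other 7. Their mean correlations with the remaining arrays were 0.972 and 0.981, against 0.989 to 0.991 for the others. Sham 2 had the highest adipocyte marker score, a mean log2 deviation from the gene means of 1.00, and its extracellular matrix score was −0.51. Testosterone 2 scored 0.83 for adipocyte markers and 0.86 for macrophage and lymphocyte markers. All 3 castration arrays scored between −0.49 and −0.47 for adipocyte markers, while testosterone 1 scored 0.29 and testosterone 3 scored −0.39. Counts of genes passing, of genes at an unadjusted p under 0.05 and of lists called are therefore also given without sham 2 and testosterone 2, a setting chosen after these arrays had been seen to stand apart.

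**Figure D1:**
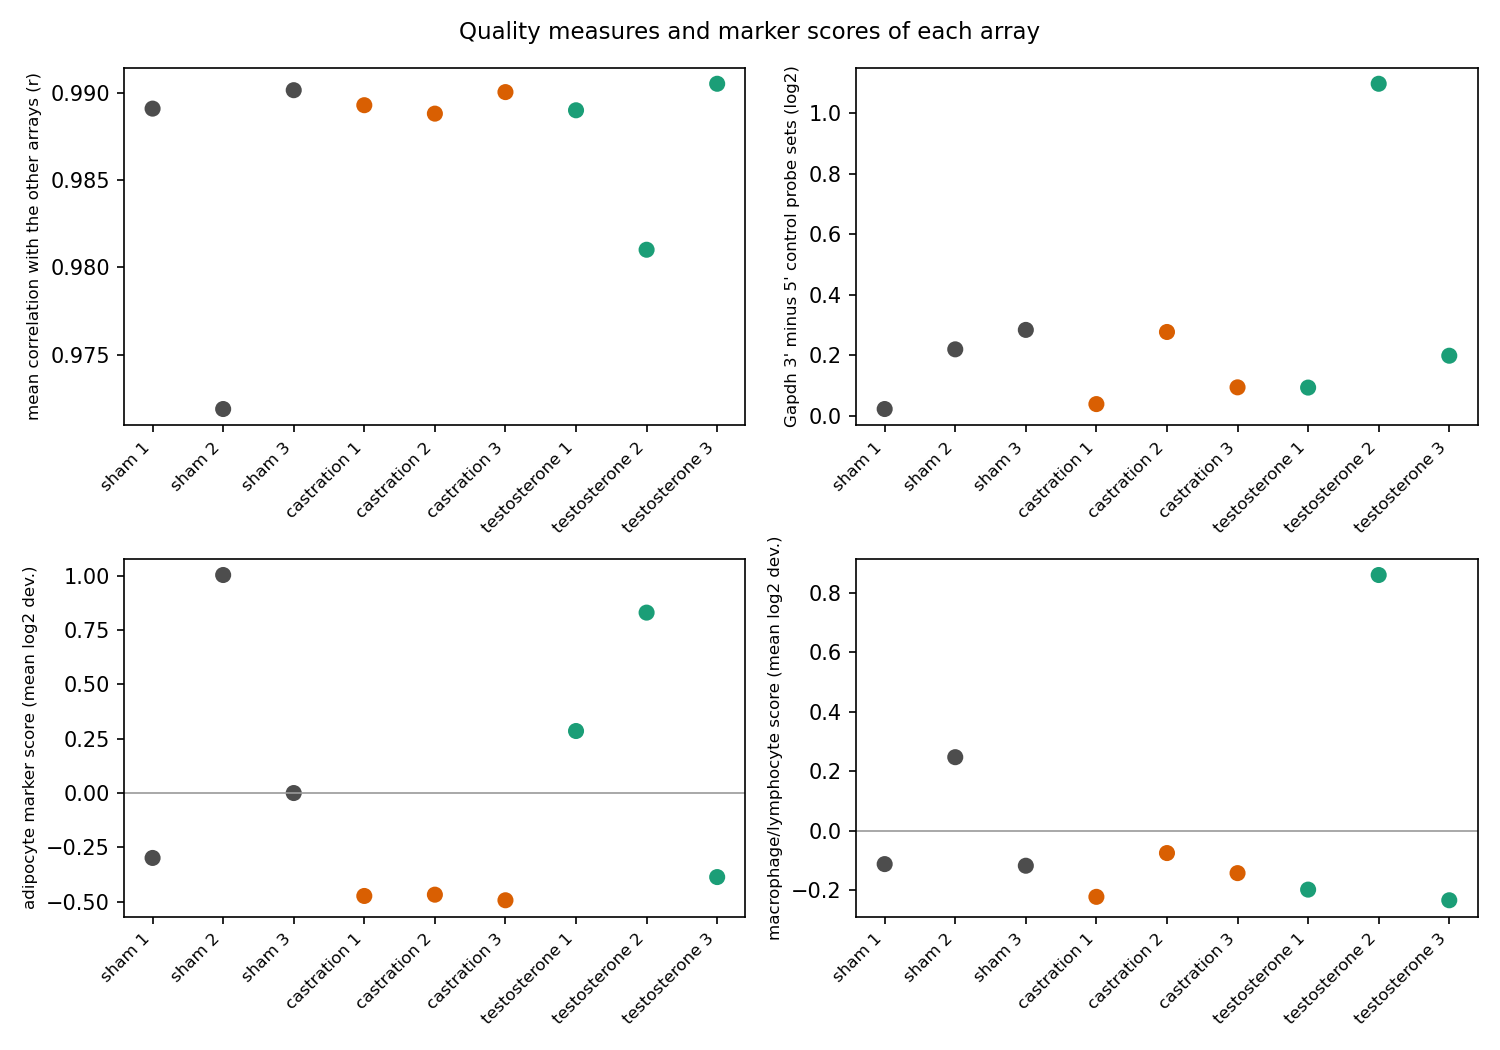
Each point is 1 array (horizontal axis; grey sham, orange castration, green testosterone). The panels show the mean correlation with the other arrays (Pearson's r across all probe sets except controls), the Gapdh 3′ minus 5′ control difference (log2), and the adipocyte and macrophage/lymphocyte scores (mean log2 deviation of the markers). Sham 2 has the lowest mean correlation, 0.972, and testosterone 2 has the highest 3′ minus 5′ difference, 1.10.

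The castration effect was read from castration against sham. Single genes of polyamine metabolism, hormone response and the clock differed, while the polyamine and androgen response lists as wholes were not called. Smox, spermine oxidase of the polyamine pathway, averaged 10.12 ± 0.49 (SD, n = 3) in sham and 7.87 ± 0.33 after castration, a 4.77-fold lower level. Odc1, ornithine decarboxylase, the rate-limiting enzyme of polyamine synthesis, was lower by log2 1.14, and Fkbp5, an immunophilin induced by androgens and glucocorticoids, was 2.22-fold lower. The clock output factor Dbp was 2.17-fold higher after castration, the p53-responsive Sesn1 was 2.55-fold higher, and the muscle transcription factor Myog was 2.31-fold higher. For each of these genes the 3 castration arrays lay wholly on 1 side of the 3 sham arrays. None passed the limma test adjusted over all genes, and each passed adjusted over the fixed list it belongs to.

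Over all 18193 genes, 0 passed an adjusted p of 0.05 in this comparison, and the smallest adjusted p was 0.103. At an unadjusted p under 0.05, 562 genes were higher and 297 lower after castration, 859 together, where chance gives 909.65. This count was 978 without sham 2 and testosterone 2, 3295 with array weights and 483 to 2275 leaving out 1 array, highest without sham 3, so it lay on either side of chance. The arrays of the 2 groups did not overlap in 8.89% of genes, where chance gives 10%. With array weights, which count an array less the further it strays from its group, 97 genes were higher and 77 lower. The weights were 4.61 for sham 1, 0.164 for sham 2 and 0.644 for sham 3, so these calls rest mostly on 1 sham array. Without sham 2 and testosterone 2, 5 were higher and 13 lower, and all 18 were also called with weights. Without sham 2 alone, 7 genes passed.

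The smallest p-values, none of them passing over all genes, belonged to Dbp, Abhd18, Slc7a2, Per3 and Aldh7a1 among genes higher after castration. Their log2 differences were 1.11, 1.31, 1.09, 0.89 and 0.66, with adjusted p of 0.103 for Dbp, Abhd18 and Slc7a2, 0.106 for Per3 and 0.141 for Aldh7a1. Slc7a2 is a cationic amino acid transporter, and Aldh7a1 an aldehyde dehydrogenase of lysine breakdown. Abhd18 averaged 3.31 in sham and 3.19 with testosterone, close to the array medians of 3.15 to 3.26, so the size of its difference is uncertain. Only 3 of the 6 probe sets of Per3 shared this sign, as did 3 of 4 for Slc7a2 and 2 of 3 for Aldh7a1. Among genes lower after castration they belonged to Smox, Mss51, Spns2, Inmt and Fkbp5, with log2 differences of −2.26, −0.97, −1.50, −1.43 and −1.15. Adjusted p was 0.103 for Smox, Mss51 and Spns2, 0.119 for Inmt and 0.271 for Fkbp5. Mss51 is a mitochondrial protein of skeletal muscle, Spns2 a sphingosine-1-phosphate transporter and Inmt an indolethylamine methyltransferase.

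Of 31 gene lists fixed beforehand, 10 were called by the set test (camera), 8 of them toward higher expression after castration. With an estimated correlation between genes none of the 10 held: adjusted p was 0.498 for the circadian list and 0.619 for the other 9. The circadian list and the epidermal list held without sham 2 and testosterone 2, each at adjusted p = 0.0161, and the androgen response list was called toward lower expression at the same adjusted p. The epidermal score was 0.15 on sham 1 and 0.48 on sham 2. On sham 3 it was −0.07, within the castration range of −0.16 to −0.05, so without sham 2 the epidermal call rests mostly on sham 1. Without sham 2 alone, 3 lists were called.

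In the atrophy and autophagy list, 21 of 31 measured members were higher after castration (median log2 0.17, adjusted p = 0.00418). Adjusted over the list alone, Sesn1, Ctsl and Gadd45a rose, by log2 1.35, 0.94 and 0.39, and 28 members did not pass. Ctsl encodes the lysosomal protease cathepsin L, and its second probe set had the opposite sign. Fbxo32 and Trim63, the muscle ubiquitin ligases atrogin-1 and MuRF1, differed by −0.16 (SE 0.15) and −0.11 (SE 0.11). Without sham 2 the list's median was 0.08 (adjusted p = 0.0700), and without testosterone 2 as well its adjusted p was 0.0948.

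The proteasome list had 25 of 31 members higher (median 0.08, adjusted p = 0.0201), with no member passing. Psmc6, Psmb5 and Psma4 differed by 0.33, 0.18 and 0.41. Its median was −0.01 after renewed quantile normalisation, and 0.01 without sham 2 (adjusted p = 0.598). The IGF and mTOR list had 25 of 30 members higher (median 0.29, adjusted p = 0.00128), again with no member passing. Grb10, an adaptor that restrains insulin and IGF receptor signalling, differed by 1.25, Ddit4l by 0.39 and Igfbp3 by 0.39. Only 1 of the 3 probe sets of Grb10 had this sign. Igf1 was at 3.86 on sham 2 against 6.28 to 6.99 on the other sham and the castration arrays. Its difference of 0.83 (SE 0.77) became −0.13 without sham 2, and the list's median became 0.07 (adjusted p = 0.285).

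The circadian list had 11 of 18 members higher (median 0.21, adjusted p = 0.00875), and Dbp and Per3 rose, adjusted over the list alone. Its adjusted p was 0.0594 without sham 3. The calcium handling list had 21 of 27 members higher (median 0.12, adjusted p = 0.00875). Adjusted over the list alone, Ppp3ca, a calcineurin catalytic subunit, rose by 0.34 and Cacnb1, a calcium channel subunit, by 0.50. In the heat shock list 16 of 19 members were higher (median 0.15, adjusted p = 0.00384), with none passing. Hsp90aa1, Dnaja1 and Dnajb1 differed by 0.66, 0.53 and 0.69. Without sham 2 the calcium handling and heat shock medians were 0.05 (adjusted p = 0.263) and 0.08 (adjusted p = 0.285).

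The lists called in the same comparison included markers of cells other than muscle fibres, and most of these calls depended on sham 2. Adipocyte markers were lower after castration in 11 of 12 members (median −0.61, adjusted p = 0.00212), with none passing. Adipoq averaged 8.02 ± 1.27 (SD, n = 3) in sham and 5.47 ± 0.15 after castration, Retn differed by −1.37 and Cidec by −1.01. Sham 2 alone had an adipocyte score of 1.00, and without it the median was −0.14 with an adjusted p of 0.285. Epidermal and hair markers were lower in 12 of 12 members (median −0.24, adjusted p = 8.32e-05), among them Krtdap at −0.48, Krt1 at −0.34 and Krt5 at −0.32, all of them dim. Extracellular matrix genes were higher in 33 of 41 members (median 0.21, adjusted p = 0.00128), with Col14a1 at 0.85, Postn at 0.57 and Bgn at 0.49. Endothelial markers were higher in 15 of 18 members (median 0.21, adjusted p = 0.0258), with Ramp2 at 0.61, Esam at 0.40 and Flt1 at 0.49. Without sham 2 the matrix median was 0.03 (adjusted p = 0.641) and the endothelial median 0.07 (adjusted p = 0.285). The endothelial list was also lost without sham 3 (adjusted p = 0.0531) and without castration 1 (0.141), and the proteasome list without castration 1 (0.0551).

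The remaining 21 lists were not called in this comparison. The fry test for members changed in either direction, a further test beside the directional one, gave an adjusted p of 2.15e-05 for the circadian, 0.000149 for the polyamine, 0.00034 for the glucocorticoid response, 0.00249 for the atrophy and 0.0042 for the neuromuscular junction list. This test asks whether any members changed, not whether the list changed more than other genes, so a few strong members can carry it. It was run with all arrays only. Single members passed in several lists, adjusted over the list alone. In the polyamine list Smox and Odc1 fell and Oaz2, an antizyme that restrains ornithine decarboxylase, rose by 0.39, while the list's set test gave an adjusted p of 0.763. Without sham 2 and testosterone 2, Oaz2 did not pass over the list. Fkbp5 fell in the androgen response list, whose median was 0.10, mean −0.05 and test direction lower (adjusted p = 0.640). Myog rose by 1.21 in the myogenic list and, with Gadd45a, in the neuromuscular junction list. Ppp1r3c, which targets a phosphatase to glycogen, fell by 0.68 in the glycolysis and glycogen list. In the fibroblast list Gsn fell by 0.42 and Col14a1 rose by 0.85, but Col14a1 did not pass over that list without sham 2 and testosterone 2. The myosin heavy chains Myh1, Myh2, Myh4 and Myh7 differed by −0.17, 0.09, 0.05 and 0.14, none passing, and the sign of Myh4 turned after renewed quantile normalisation. Of the genes named here, 1 probe set had the opposite sign for Oaz2 (of 3), Cacnb1, Flt1 and Igf1 (each of 4) and Hsp90aa1 (of 5).

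**Figure D2:**
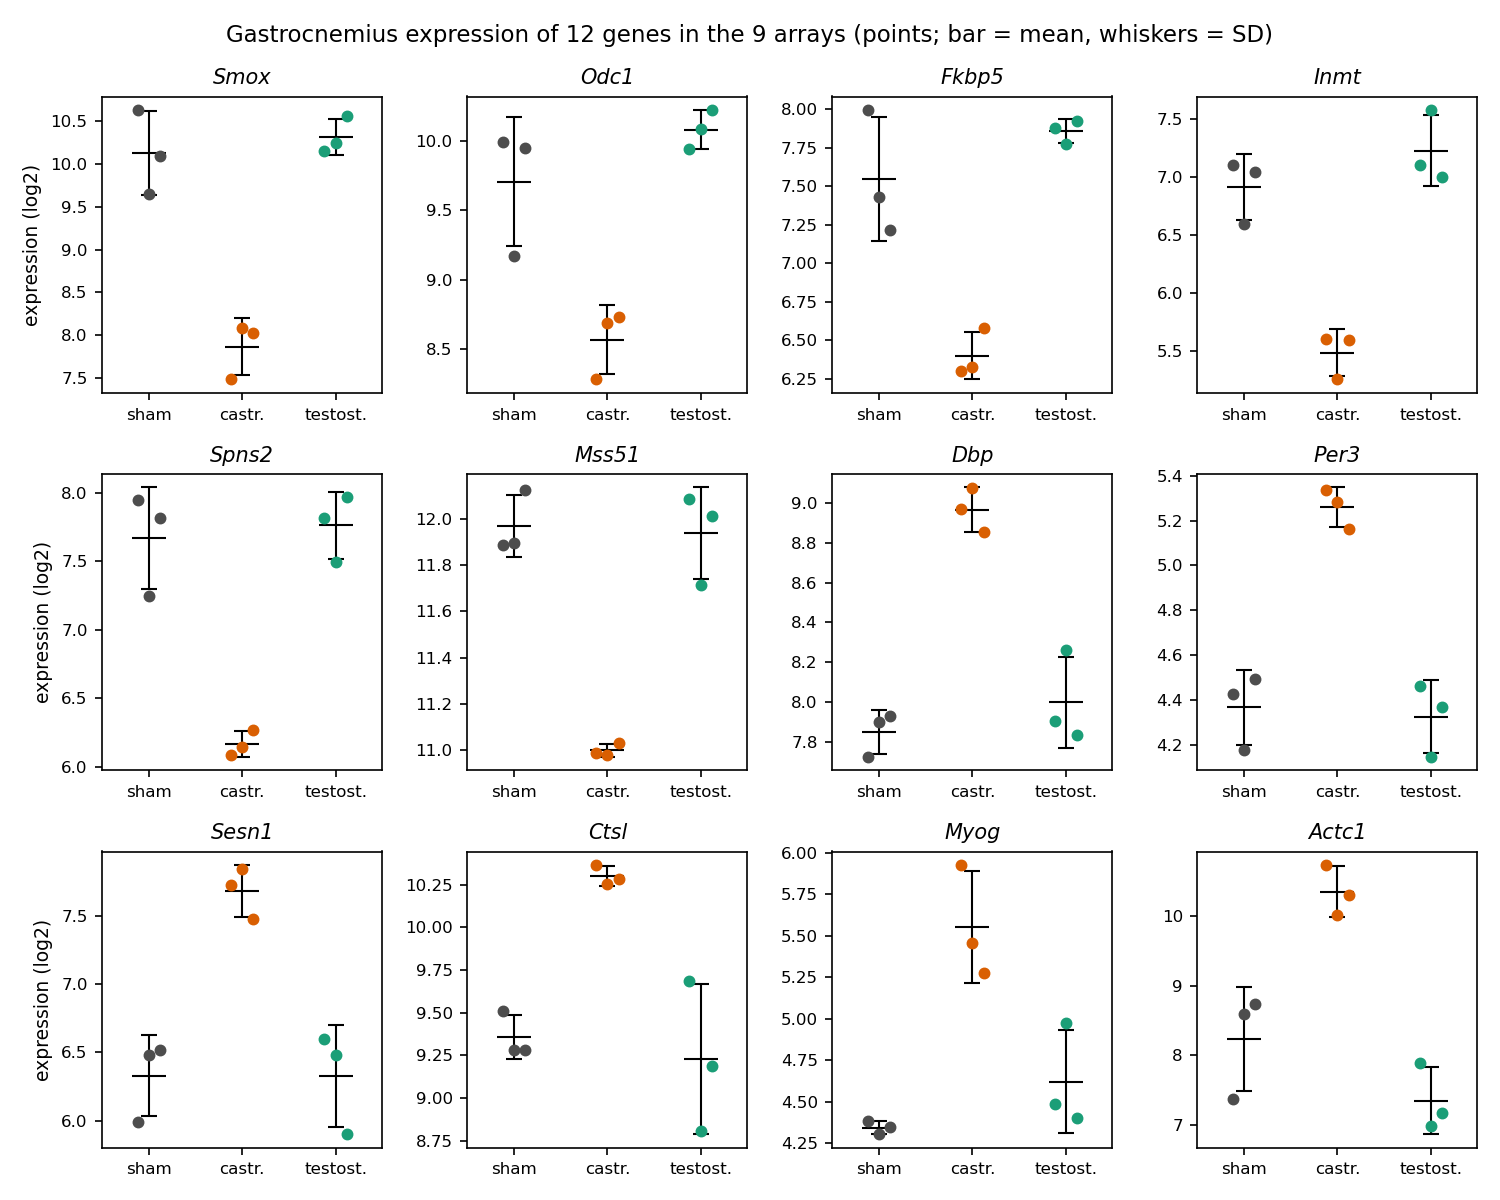
Log2 expression (vertical axis, scaled to each gene) of 12 genes on the 3 arrays of each group (points; horizontal bar, mean; whiskers, SD). Smox, Odc1, Fkbp5, Inmt, Spns2 and Mss51 are lower on all 3 castration arrays than on the other 6, and Dbp, Per3, Sesn1, Ctsl, Myog and Actc1 are higher.

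The testosterone replacement effect was read from testosterone against castration. Of the 50 genes with the smallest p in each comparison with castration, 29 were shared, all with the opposite sign. Both comparisons use the same castration arrays, which by itself gives such overlap. Simulations of unchanged groups gave 4.39 shared genes on average. Smox averaged 10.32 ± 0.21 (SD, n = 3) with testosterone, 5.45-fold above castration. Odc1 was 2.86-fold, Fkbp5 2.75-fold and Slc38a2, a neutral amino acid transporter, 2.45-fold above castration. Actc1, the cardiac alpha-actin that is also expressed in developing and regenerating muscle, averaged 7.35 ± 0.48 with testosterone and 10.35 ± 0.36 after castration, about 8-fold lower. As a group, extracellular matrix genes were lower with testosterone, in 35 of 41 members, a call that did not hold with an estimated correlation between genes (adjusted p = 0.608). For each of the 5 named genes the 3 testosterone arrays lay wholly on 1 side of the castration arrays.

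No gene passed over all genes here either: 0 of 18193, with a smallest adjusted p of 0.0610. At an unadjusted p under 0.05, 299 genes were higher and 334 lower with testosterone, 633 together, where chance gives 909.65. This count was 1051 without sham 2 and testosterone 2, 1281 with array weights and 394 to 1093 leaving out 1 array, highest without sham 2, so it too lay on either side of chance. The arrays did not overlap in 9.01% of genes, where chance gives 10%. With array weights 36 genes were higher and 23 lower. Leaving out sham 2 and testosterone 2 gave 20 higher and 7 lower, and all 27 were also called with weights. Without sham 2, which enters only through the pooled spread, 28 genes passed, and without sham 1, 3 did.

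The smallest p-values among genes higher with testosterone were those of Smox, Tfcp2l1, Inmt, Spns2 and Mss51, with log2 differences of 2.45, 1.38, 1.74, 1.60 and 0.94. Tfcp2l1 is a transcription factor, and 2 of its 3 probe sets had this sign. Among genes lower with testosterone they were those of Abhd18, Per3, Actc1, Dbp and Slc7a2, with −1.42, −0.93, −3.0, −0.97 and −0.99. Adjusted p was 0.0804 for Slc7a2 and 0.0610 for the other 9, so none passed. Abhd18 shared its sign in 2 of 3 probe sets and Slc7a2 in 3 of 4.

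The set test called 9 lists, 4 toward higher and 5 toward lower expression with testosterone, and none held with an estimated correlation (adjusted p = 0.608 for each). Without sham 2 and testosterone 2, 5 of the 9 held: androgen response, lipid and sterol synthesis, extracellular matrix, adipocyte and endothelial. Without testosterone 2 alone 4 lists were called, and without castration 3, 15 were.

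Androgen response genes were higher with testosterone in 25 of 34 members (median 0.08, mean 0.23, adjusted p = 0.00183). Adjusted over the list alone, Fkbp5 rose by 1.46 (SE 0.18) and Slc38a2 by 1.29 (SE 0.25). Lipid and sterol synthesis genes were higher in 21 of 30 members (median 0.24, adjusted p = 7.94e-05), and Lpin1, a phosphatidate phosphatase of triglyceride synthesis, rose by 0.63, adjusted over the list alone. The score of the lipid list went with the adipocyte score: it was 0.26 on testosterone 1, 0.46 on testosterone 2 and 0.28 on sham 2, whereas testosterone 3, at −0.20, lay within the castration range of −0.35 to −0.09. A difference in fat content is therefore not separated from a testosterone effect on these genes. Adipocyte markers were higher in 11 of 12 members (median 0.60, adjusted p = 0.000116), with none passing. Adipoq differed by 2.24, Pck1 by 0.96 and Car3 by −0.21. Car3 was at 13.09 to 13.44 on all arrays, including the castration arrays with Adipoq at 5.29 to 5.58, so it did not track Adipoq here. The arrays testosterone 1 and testosterone 2 had adipocyte scores of 0.29 and 0.83, while testosterone 3, at −0.39, lay near the castration arrays (−0.49 to −0.47). The adipocyte median was 0.27 without sham 2 and testosterone 2. In that setting the adipocyte and lipid list calls rest mostly on testosterone 1. Macrophage and lymphocyte markers were higher in 20 of 24 members (median 0.21, adjusted p = 0.0101). Of these, Cd79a, a B cell receptor component, differed by 0.84, H2-Aa by 0.79 and Adgre1 by 0.12, none passing. The median of that list was −0.05 without testosterone 2 (adjusted p = 0.639), and its adjusted p was 0.0838 without castration 1.

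Extracellular matrix genes had a median of −0.24 (adjusted p = 2.13e-09). No member passed with all arrays. The smallest p-values were those of Col3a1 at −0.57, Sparc at −0.66 and Col14a1 at −0.85. Without sham 2 and testosterone 2 the median was −0.28 and 12 members were lower, adjusted over the list alone. Tendon markers were lower in 9 of 13 members (median −0.16, adjusted p = 0.0177), with Cilp2 at −0.39, Kera at −0.90 and Comp at −0.35. That call was lost without castration 2 (adjusted p = 0.172), testosterone 2 (0.0997) or testosterone 3 (0.0693). Endothelial markers were lower in 15 of 18 members (median −0.20, adjusted p = 0.00853). Cldn5, a tight junction protein, differed by 0.38 against that direction, and Tie1 and Cav1 by −0.40 and −0.36. That call was lost without castration 1 (adjusted p = 0.0838), testosterone 2 (0.0641) or testosterone 3 (0.0611).

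The atrophy and autophagy list was lower with testosterone in 21 of 31 members (median −0.16, adjusted p = 0.0171), but its members split. Adjusted over the list alone, Sesn1, Ctsl and Gadd45a fell, by 1.35, 1.07 and 0.37. Fbxo32, Map1lc3a and Trim54 rose, by 0.71, 0.75 and 0.28, where Map1lc3a is an autophagosome protein and Trim54 a sarcomeric ubiquitin ligase, both named after their values were seen. The call was lost without castration 1 (adjusted p = 0.0838), castration 2 (0.0804), testosterone 2 (median −0.06, 0.140) or testosterone 3 (0.0678). The IGF and mTOR list was lower in 20 of 30 members (median −0.15, adjusted p = 0.00335), and Ddit4l, an inhibitor of mTOR signalling, fell by 0.47, adjusted over the list alone. Its median was −0.04 without testosterone 2 (adjusted p = 0.0997). Igf1 differed by −0.69 (SE 0.77) and Trim63 by 0.29 (SE 0.11), neither passing.

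The fry test for members changed in either direction gave an adjusted p of 6.55e-06 for the circadian, 0.000104 for the glucocorticoid response, 0.000302 for the polyamine and 0.00195 for the atrophy list. Here too it was run with all arrays only, and a few strong members can carry it. Outside the called lists, single members again passed adjusted over their list alone. Smox and Odc1 rose in the polyamine list (set test adjusted p = 0.383; median −0.01, mean 0.23). Dbp and Per3 fell in the circadian list (0.0742). Fkbp5, Zbtb16 and Hsd11b1 rose and Sesn1 fell in the glucocorticoid response list (0.0682), Zbtb16 by 1.15 and Hsd11b1, which regenerates active glucocorticoid, by 1.08. Myog fell by 0.93, and Ppp1r3c rose by 0.75 on 1 of its 2 probe sets, the other having the opposite sign. Myh1, Myh2, Myh4 and Myh7 differed by 0.08, −0.10, −0.02 and 0.33, none passing, and the sign of Myh4 turned after renewed quantile normalisation. Opposite signs were shown by 1 probe set of Sparc (of 3), Igf1 (of 4), Myh1 (of 3) and Myh4 (of 2).

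**Figure D3:**
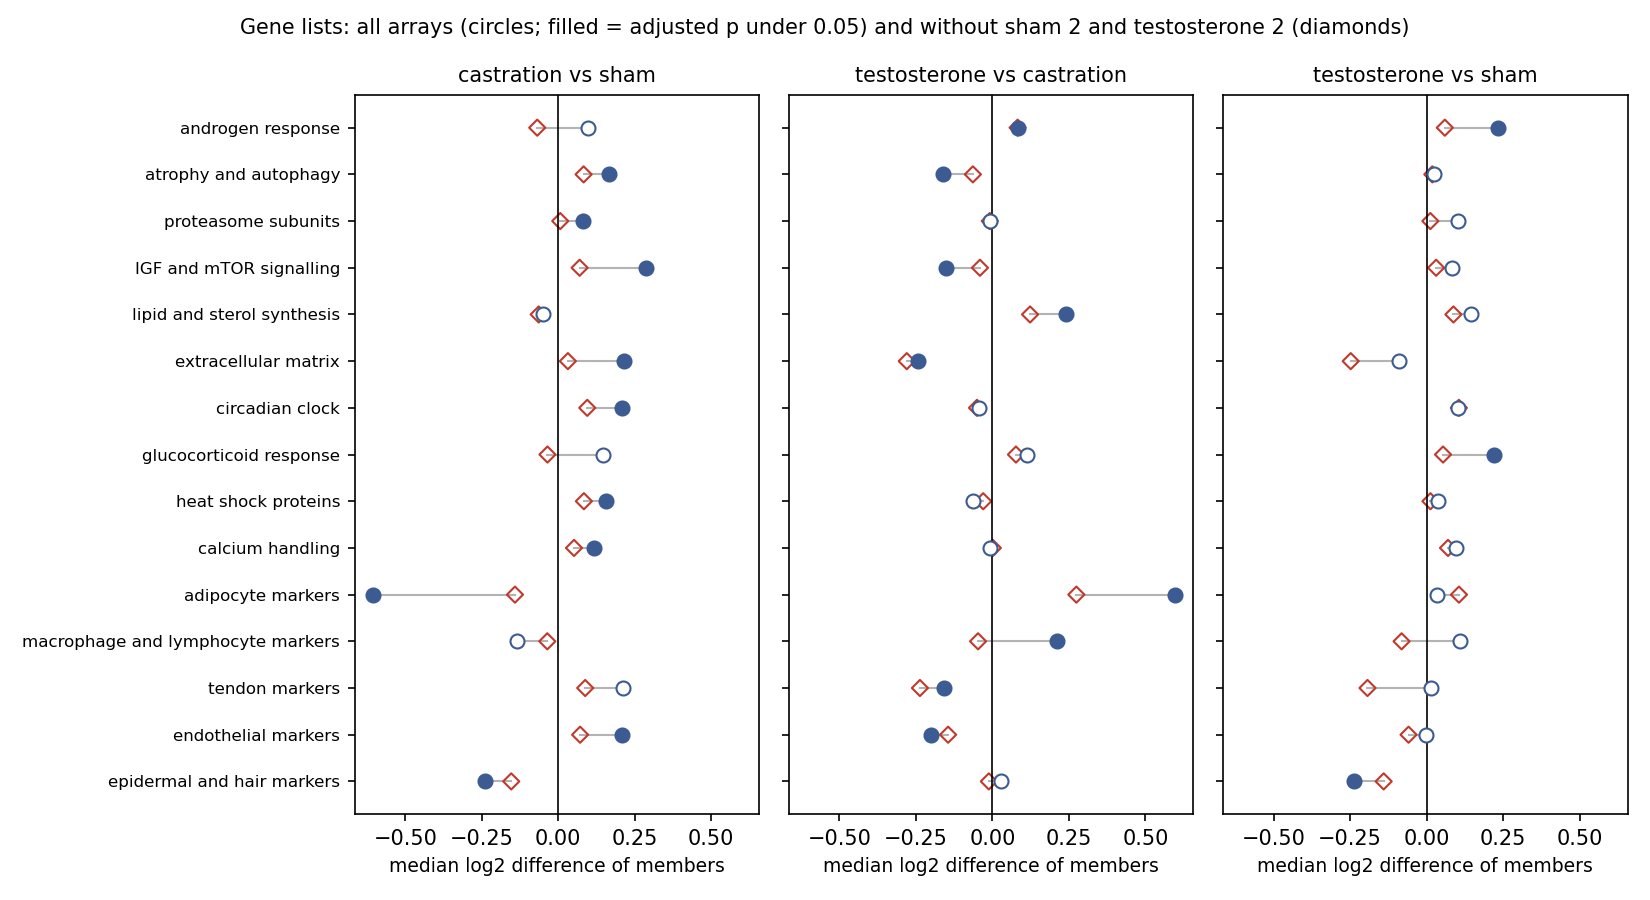
Median log2 difference of the members (horizontal axis) of the 15 lists called in at least 1 comparison (vertical axis), 1 panel per comparison. Circles are all 9 arrays, filled where the set test with preset correlation gave an adjusted p under 0.05, and diamonds leave out sham 2 and testosterone 2. The extracellular matrix median in testosterone against castration is −0.24 with all arrays and −0.28 without those arrays, whereas the macrophage and lymphocyte median goes from 0.21 to −0.05.

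Whether testosterone returned the genes that castration changed was counted next. With all arrays alike, 0 genes were called in castration against sham, so 0 were returned, and the moderated F test over the 3 groups also gave 0 (smallest adjusted p = 0.0752; 662 genes at an unadjusted p under 0.05). Among the 50 genes with the smallest p in each of the comparisons with castration, 29 were shared, and all 29 had opposite signs, where independent lists of that size would share 0.137. Both comparisons share the castration arrays, which by itself gives overlap with opposite signs. In 100 simulations of unchanged groups with these arrays shared, a mean of 4.39 genes overlapped (0 to 8). With array weights 50 genes were called in both comparisons, all 50 with opposite signs, against 0.275 for independent lists. When sham 2 and testosterone 2 were left out it was 15 of 15, against 0.0162. The simulations leave out real effects and draw each gene independently, and the independent lists leave out the sharing. Genes that vary together could widen the simulated ranges. The 3 castration arrays were not split, since at least 1 comparison would have kept a single castration array, so part of the excess of these overlaps can come from sharing them. The F test gave 99 and 25 genes in these settings, and without sham 2 alone it gave 12, with 6 genes returned. The covariance of their log2 differences across genes was −0.0207, against −0.00748 in 100 simulations of unchanged groups (−0.00853 to −0.00638). The observed covariance, different by −0.0132 from the simulated mean, lies beyond the simulated range. Since simulated genes varied independently, sharing the arrays is not excluded as the source of that difference. The correlation was −0.495 against −0.248.

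The overall effect was read from testosterone against sham. No gene passed: 0 of 18193 by limma, 0 with array weights and 0 without sham 2 and testosterone 2, with a smallest adjusted p of 0.780. At an unadjusted p under 0.05, 481 genes were higher and 310 lower with testosterone, 791 together, where chance gives 909.65. This count was 569 without sham 2 and testosterone 2, 2399 with array weights and 505 to 2479 leaving out 1 array, highest without sham 3. The arrays did not overlap in 6.47% of genes, where chance gives 10%. Without testosterone 3, 1 gene passed. Smox, Odc1 and Fkbp5 differed by 0.19 (SE 0.26), 0.38 (SE 0.22) and 0.31 (SE 0.18), each within about 2 SE of 0. The sign of Smox turned without sham 2 (−0.04), and only 1 of the 3 probe sets of Fkbp5 had this sign. Ppargc1a, a coactivator of mitochondrial genes, averaged 6.77 ± 0.55 (SD, n = 3) in sham, 7.55 ± 0.39 after castration and 8.18 ± 0.27 with testosterone. Its difference of 1.42 passed adjusted over the fatty acid oxidation list alone, but not over all genes, and without sham 2 and testosterone 2 it did not pass over the list either.

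The genes with the smallest p besides Ppargc1a, all at an adjusted p of 0.780, were Scaper, Fbrsl1, Malat1 and Dgkd, with differences of 0.67, 0.58, 0.88 and 0.52. On the lower side they were Syne4, Abca2, Clec4g, Nbl1 and Ap5s1, with −0.44, −0.40, −0.33, −0.36 and −0.39. Probe sets disagreed in sign for Dgkd (2 of 4 alike), Clec4g (1 of 2), Fbrsl1 (2 of 3), Malat1 (6 of 7), Iqgap2 (1 of 2), Tsc22d3 (3 of 4), Fbxo32 (2 of 3) and Igf1 (2 of 4). Fbxo32 differed by 0.56 (SE 0.15), Trim63 by 0.18 (SE 0.11) and Igf1 by 0.14 (SE 0.77). Igf1 was at 4.87 on testosterone 2 and 3.86 on sham 2, and its difference was −0.30 without both. Myh1, Myh2, Myh4 and Myh7 differed by −0.09, −0.01, 0.03 and 0.46, none passing, and the sign of Myh2 turned when arrays were rescaled.

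The set test called 3 lists in this comparison. Androgen response genes were higher in 27 of 34 members (median 0.23, adjusted p = 0.0419, and adjusted p = 0.882 with an estimated correlation), with Azgp1 at −0.48, Iqgap2 at −0.23 and Srf at 0.39 having the smallest p. Glucocorticoid response genes were higher in 20 of 24 members (median 0.22, adjusted p = 0.0326, and adjusted p = 0.846 with an estimated correlation), with Cebpd at 0.69, Zbtb16 at 0.56 and Tsc22d3 at 0.27. Epidermal and hair markers were lower in 11 of 12 members (median −0.24, adjusted p = 0.00169, and adjusted p = 0.846 with an estimated correlation), with Krt14 at −0.34, Krt15 at −0.33 and Krtdap at −0.51. No member of these lists passed. Without sham 2 the androgen response adjusted p was 0.526, and it was 0.169 without testosterone 1. The glucocorticoid adjusted p was 0.116 without sham 3 and 0.129 without testosterone 2. Without sham 2 and testosterone 2, 9 lists were called. The epidermal list was among them (adjusted p = 0.0113), although the epidermal score of sham 3, −0.07, lay within the testosterone range of −0.15 to −0.04. The extracellular matrix list was lower in that setting (median −0.25, adjusted p = 5.75e-17), where all arrays gave −0.09 and an adjusted p of 0.142. In that setting fibroblast markers (median −0.18, adjusted p = 0.000226), tendon markers (median −0.19, adjusted p = 0.00367) and macrophage and lymphocyte markers (median −0.08, adjusted p = 0.00424) were lower as well. So were the lists of blood cells (median −0.08, adjusted p = 0.0162), oxidative phosphorylation (median −0.04, adjusted p = 0.0256) and Schwann cells (median −0.11, adjusted p = 0.0316), and the circadian list was higher (median 0.11, adjusted p = 0.0185). All 9 calls use the preset correlation, and with all arrays the adjusted p with an estimated correlation lay between 0.846 and 0.979 for these lists. The number of lists was 7 without sham 1, 8 without sham 2 and 5 without testosterone 3.

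The lists called in no comparison with all arrays, of which oxidative phosphorylation, blood cells, fibroblasts and Schwann cells were called in testosterone against sham without sham 2 and testosterone 2, are given with their adjusted p for castration against sham, testosterone against castration and testosterone against sham, in that order. Contractile genes gave 0.640, 0.383 and 0.235 for the fast fibre list and 0.640, 0.403 and 0.294 for the slow fibre list. Metabolic lists gave 0.640, 0.0725 and 0.0580 for oxidative phosphorylation, 0.442, 0.659 and 0.935 for fatty acid oxidation and 0.640, 0.974 and 0.669 for glycolysis and glycogen. Polyamine metabolism gave 0.763, 0.383 and 0.235. Growth and regeneration lists gave 0.191, 0.383 and 0.818 for myostatin, activin and BMP signalling, 0.191, 0.800 and 0.299 for myogenic regulation, 0.183, 0.0657 and 0.944 for the neuromuscular junction, 0.360, 0.974 and 0.465 for ribosomal proteins and 0.335, 0.974 and 0.367 for the cell cycle. Immediate early genes gave 0.640, 0.106 and 0.142. Markers of other cells gave 0.117, 0.878 and 0.238 for blood cells, 0.191, 0.0725 and 0.753 for fibroblasts, 0.0526, 0.383 and 0.358 for smooth muscle and pericytes and 0.191, 0.800 and 0.159 for Schwann cells and nerve.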

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

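The tests of RNA quality and of fibroblast content as sources of the extracellular matrix difference, and the setting without arrays sham 2 and testosterone 2, were chosen only after the results had been seen. Groups of 3 arrays are too small for a search for outliers.

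Control probe sets outside the tested genes set array testosterone 2 apart from the sham arrays. Its Gapdh 3′ signal exceeded the 5′ signal by 1.10 (log2), where the highest sham array had 0.284 (SD of the sham arrays 0.136). For actin the difference was 1.56 against 0.628 (SD 0.242), and the 18S rRNA control was at 12.9 against 11.7 (SD 0.358). Among the 9160 probe sets the annotation does not list, adjusted over these alone, 2 passed in castration against sham and 3 in testosterone against castration. The 2 differed by 0.90 and −1.20 after castration, and by −1.02 and 1.30 with testosterone, and the further one by 1.68 with testosterone.

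No gene passed in either comparison with castration when all arrays counted alike, while array weights gave 174 and 59, and leaving out sham 2 and testosterone 2 gave 45 over both. The other 8 pairs of 1 sham and 1 testosterone array gave at most 23, reached with sham 2 in the pair. Leaving out sham 2 alone gave 7 and 28 genes and testosterone 2 alone, or with sham 1 or sham 3, gave 0, so the spread of sham 2 more than that of testosterone 2 may keep genes from passing. Chance calls made by the weights are not excluded: with weights estimated anew, 6 of 100 regroupings of the 9 arrays gave at least the real 99 genes by the F test, the highest other 3307. The other 5 are among 30 regroupings whose weights did not converge, with highest weights of 13.5 to 75.6. Of the 70 that converged only the real one reached 99. The next highest of these gave 84, and it kept the castration arrays together while mixing sham with testosterone. Chance calls by the weights and an untested biological difference between the pools stay open.

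Extracellular matrix genes were lower with testosterone than after castration, with a median log2 of −0.244 over 41 genes (95% bootstrap interval over genes −0.370 to −0.163), but the list call did not hold with the estimated correlation of 0.396 between its genes (adjusted p = 0.608). Degraded RNA on testosterone 2 is argued against as the whole cause, since without that array the median was −0.280 (−0.390 to −0.144) and 37 of 41 genes were lower. Fewer fibroblasts in the testosterone samples cannot be told apart from a lower level per cell: 12 fibroblast markers outside the list had a median of −0.0606 with 7 lower, and the difference of 0.183 to the list has an interval that covers 0 (−0.0790 to 0.433). An effect of testosterone, the treatment that defines the groups, stays open as a hypothesis.

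Dbp and Per3 were higher on the castration arrays than on the other 6, by log2 1.04 and 0.91. If the castration animals had been sampled at another time of day, genes of the opposite clock phase would be lower there, and 5 such genes had a mean difference of −0.299 (SE 0.130), 4 of them lower, with Arntl at −0.84 and Npas2 at 0.09. A shift in sampling time may therefore account for the pattern, and the labels give no time of day. Of 8 other clock genes of the Dbp phase the mean was 0.192 (SE 0.0693), but Per2, Nr1d1 and Bhlhe41 were lower. A hormone effect on the clock would give the same signs and was not separated from it.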

How the results depend on the processing

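Leaving out arrays sham 2 and testosterone 2 together, and every value of castration against the mean of the others, were chosen only after the results had been seen; all other alternatives were planned. The 121 values of named genes kept their direction in 2622 of 2649 recomputations, and 22 list calls kept the direction of the set test in 480 of 482 and stayed called in 363. Many of the gene recomputations cannot turn a sign. The block, only 2 groups, all probe sets, the trend, robust variances and analysis without moderation leave the log2 difference unchanged. So does leaving out an array of the group not compared. Most values were also picked for small p in these data, and every gene whose sign turned belongs to the fixed set. The gene count therefore does not measure stability. The cause of a change was not tested unless a count of arrays or genes gives it. Signal near background limits the epidermal markers, Abhd18 and other genes with group means under log2 4.

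Genes called in castration against sham, 0 with all arrays, were 2 with the mean of probe sets, 2 after quantile normalisation, 2 with an intensity trend, 174 with array weights, 18 without sham 2 and testosterone 2, and 0 to 7 leaving out 1 array. In testosterone against castration, 0 became 12 with only the groups compared, 2 with the mean of probe sets, 9 without dim genes (fewer tested), 16 after quantile normalisation, 12 with a trend, 59 with weights, 27 without both arrays and 0 to 28 leaving out 1. Testosterone against sham gave 0 to 1 leaving out 1 array and 0 otherwise. The F test gave 2, 10, 7, 99 and 25 with the mean of probe sets, quantile normalisation, trend, weights and without both arrays, and 0 to 12 leaving out 1. Returned genes were 2, 2, 2, 50 and 15 in those settings and 0 to 6 leaving out 1. Castration against the others gave 10 genes, 135 with weights, 51 without both arrays and 0 to 35 leaving out 1.

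Lists called in castration against sham were 10, and 4 without dim genes, 6 after quantile normalisation, 1 with weights, 3 without both arrays and 3 to 15 leaving out 1. In testosterone against castration they were 9, and 5 without both arrays and 4 to 15 leaving out 1. In testosterone against sham they were 3, and 1 after centring, 5 with weights, 9 without both arrays and 2 to 8 leaving out 1. An estimated correlation and the directional fry test gave 0 in all 3 comparisons, while fry for either direction called 5, 4 and 0.

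With the replicate number as a block, 0 genes were called everywhere and 12, 10 and 4 lists. Deviations of same-numbered arrays correlated between −0.489 and 0.268, so the numbers do not pair the arrays.

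Signs turned for Igf1 in castration against sham, at −0.235 with weights, −0.130 without both arrays and −0.130 to 1.44 leaving out 1 array (negative without sham 2). In testosterone against sham Igf1 was −0.0138 with the mean of probe sets, −0.617 with weights, −0.299 without both and −0.824 to 0.742 leaving out 1 (lowest without sham 2, with −0.0756 without testosterone 1 and −0.174 without testosterone 3). Smox there was −0.184 with weights, −0.00485 without both and −0.0434 to 0.444 leaving out 1, and Fkbp5 was −0.00250 with weights.

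Myh4 was −0.00866 in castration against sham after quantile normalisation. In testosterone against castration it was 0.104 with the mean of probe sets, 0.0221 after quantile normalisation and −0.0419 to 0.0115 leaving out 1. Myh7 in castration against sham was −0.135 with weights and −0.0744 to 0.376 leaving out 1. In testosterone against castration it was −0.0201 without both and −0.0201 to 0.667 leaving out 1, and in testosterone against sham −0.0813 with weights. Myh2 in testosterone against castration was −0.178 to 0.0272 leaving out 1. In testosterone against sham it was 0.00290 after quantile normalisation, 0.0225 after centring and −0.0876 to 0.118 leaving out 1 (0.0169 without sham 3). The macrophage and lymphocyte median in testosterone against castration was −0.0470 without both and −0.0470 to 0.309 leaving out 1. The proteasome median in castration against sham was −0.01 after quantile normalisation, where the set test kept its direction.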

Other observations

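Setting castration against the mean of the sham and testosterone groups, a contrast chosen only after the planned comparisons had been seen, gave 10 genes at an adjusted p under 0.05 by limma. Lower on all 3 castration arrays than on the other 6 were Smox (−2.35, SE 0.22), Inmt (−1.58), Spns2 (−1.55), Fkbp5 (−1.30), Tfcp2l1 (−1.14) and Mss51 (−0.95). Higher were Abhd18 (1.37), Dbp (1.04), Slc7a2 (1.04) and Per3 (0.91). Adjusted p lay between 0.0244 and 0.0432. All 10 were also called among the 135 genes with array weights and among the 51 without sham 2 and testosterone 2. The count was 35 without sham 2, 9 without testosterone 2, 2 without sham 1 and 0 without sham 3, testosterone 1, testosterone 3 or any castration array. Next in order, none passing, came Aldh7a1 (0.62), the zinc transporter Slc30a2 (−1.54) and the hairless corepressor Hr (−1.29), with Actc1 (2.56), all at an adjusted p of 0.0561. Hr and Slc30a2 lie outside the rule for named genes and were chosen after their values were seen.

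Pools of 1 group differed in slow fibre genes more than the groups did. The slow fibre score, a mean log2 deviation from the gene means, was 0.35 on sham 1, 0.38 on castration 1, 0.38 on testosterone 2 and 0.27 on testosterone 3, and between −0.45 and −0.19 on the other 5 arrays. Myh7 ranged from 11.20 to 12.60 over the arrays. On testosterone 2 the B cell gene Cd79a was at 5.72.

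Other groupings of the arrays were refitted. For castration against the other groups, 2 of 100 regroupings gave at least the real 10 genes, the highest other giving 15, and both set the castration arrays alone. That contrast was picked after castration had been seen to stand apart, which the regroupings make no allowance for, so chance is not excluded. For the F test without sham 2 and testosterone 2, 2 of 100 regroupings of 7 arrays gave at least the real 25 genes, the highest other giving 60. The 3 regroupings that keep the castration arrays together gave 22 to 60 genes, and all others 0, so the counts do not separate sham from testosterone. The arrays to leave out were picked after the data had been seen, with no allowance for that choice, so chance is not excluded here either. With all arrays the real F count was 0, which 100 of 100 regroupings reach by definition (highest other 2), so that test decides nothing. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. For genes the real count was 0, so 10 of 10 splits reached it in each comparison, the highest other 0. For lists, 4 of 10 gave at least the real 10 in castration against sham (highest other 15), 3 of 10 at least the real 9 in testosterone against castration (highest other 10) and 9 of 10 at least the real 3 in testosterone against sham (highest other 14).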
